A study of Rattus norvegicus with 70 samples.

How the data were processed

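Total RNA was extracted with TRIzol from liver, kidney, thyroid, testis and ovary, and libraries were made with the QuantSeq 3′ mRNA-Seq kit, per the labels' protocols. FastQC, Bowtie2, bedtools and edgeR are named, with the rat build rn6 and no versions, in the submitters' processing notes. The deposited table holds counts per gene for 70 libraries, whole numbers in 17048 rows, per the file headers and a check of every value. Of these rows, 316 carry one of 149 symbols that occur more than once and were kept as separate rows, and 2152 are named only by an identifier. How reads with several alignments or overlapping genes were counted, and whether strand was used, is not stated, so values of near-identical family members, of overlapping genes and of antisense pairs are uncertain; this concerns among others the glutathione transferases, the cytochromes P450, the Akr1c genes and the globins. No genome or annotation was used here and no coordinates are given.

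Libraries were grouped by the organ, sex and treatment in the labels, giving 3 treatment groups in each of 8 combinations of organ and sex. Total counts were 6814781 to 10837533 in male liver, 6071150 to 8940809 in female liver, 4910450 to 10218159 in male kidney, 4803807 to 7186849 in female kidney, 6726403 to 9755716 in male thyroid, 6323055 to 8023116 in female thyroid, 7432039 to 10929957 in testis and 5519794 to 7815011 in ovary. Sample codes recur across organs in the labels, which makes it apparent that organs of the same animals were sequenced; no comparison sets organs of 1 animal against each other. The sexes of all libraries were checked with the Y-linked gene Eif2s3y. Ddx3y did not separate the sexes in liver, kidney or thyroid, where males had from 0 to 22.6 and females up to 3.90 CPM. No pair of libraries within a treatment group of an organ and sex was a near duplicate. Pairs across groups were not compared.

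Each combination of organ and sex was fitted separately with edgeR 4.0.16 in R 4.3.3: low-count rows were removed with filterByExpr by treatment group, libraries were scaled with TMM, and a quasi-likelihood negative binomial model with the 3 groups was tested for BPA against vehicle, Mix against vehicle and Mix against BPA. The numbers of genes tested were 9669 and 9554 in male and female liver, 11000 and 10681 in kidney, 11119 and 11127 in thyroid, 11098 in testis and 10871 in ovary. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and an adjusted p below 0.05 counted as a change. Every adjusted p of a gene is from this edgeR test. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The 95% intervals use the same error and are not adjusted for the number of genes. They are given for genes named against vehicle in the same libraries, a choice that favours intervals away from 0. Levels are CPM as edgeR computes them, scaled with TMM, except that ribosomal RNA shares, Tnp1, Alb and the sex check use plain CPM. Sex differences were tested as interactions in a joint fit of both sexes of an organ.

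Gene lists for pathways, organ cell types and cells of neighbouring tissue were tested with camera (limma 3.58.1) on edgeR's z-scores of the counts under the negative binomial model, with a preset correlation between genes of 0.01 and again with an estimated correlation, when at least 3 genes of the list were tested; the p-values of lists were adjusted over the lists of a comparison. Members that passed were counted over all genes tested and adjusted over the list alone. Sex-biased genes, with an adjusted p below 0.05 and a log2 difference of at least 1 between the sexes, were taken from treated libraries outside the contrast in which they were tested; the thyroid gave no such set of 3 genes. Overlaps of BPA and Mix calls were set beside 20 simulations in which every library, vehicle included, was drawn from a common mean per gene. Both comparisons then used the same simulated vehicle libraries. Genes were drawn independently, so features of the real vehicle rats that run across genes were not simulated. Genes named in the text were chosen by rule: per comparison with vehicle up to 6 rising and 6 falling genes with the largest changes among those past the threshold, with a mean log2 CPM of at least 2 and groups that do not overlap; up to 3 each way for Mix against BPA; up to 4 passing members of each list; for lists of markers of other cell types, the 2 members with the most counts; up to 5 genes per sex difference; and, where none passed, the 3 with the smallest p. The result of 1 gene that the rule picked is not reported here. Tnp1 outside the testis, Alb, and clock genes that did not pass, were chosen after their values were seen. These models, lists, naming rules and the alternatives below were chosen before the data were examined, except where a test is said to have been chosen afterwards.

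The scripts were tested on simulated counts with the real means, library sizes and spreads. Changed genes were drawn only from genes above a floor of mean count. Recovery was therefore not measured for the tested genes with the fewest counts. In simulated BPA against vehicle comparisons, 100 genes changed by 4-fold were recovered in 90% of cases in male liver (9444 genes), 89% in female liver (9358), 87% in male kidney (10829), 82% in female kidney (10451), 35% in male thyroid (10882), 53% in female thyroid (10800), 93% in testis (10973) and 76% in ovary (10659). For 100 genes changed by 2-fold the shares were 44%, 35%, 37%, 14%, 1%, 3%, 64% and 46% in the same order. Among genes left unchanged in these comparisons, false calls ran from 2 in the male thyroid to 16 in the female kidney. Simulated 4-fold sex differences in the BPA effect were recovered in 60.5% of 200 genes in liver, 56.5% in kidney and 24% in thyroid.

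The alternatives were DESeq2's size factors in the edgeR fit, the Wald test of DESeq2 1.42.0, no low-count filter, the replicate number as a block, each library left out in turn, and an estimated correlation for lists; removal of the ribosomal RNA rows, their share as a covariate and removal of 1088 testis-enriched rows were added after the values were seen. Testis-enriched rows had a mean of at least 20 CPM in testis and at least 20 times that of the female kidney. Whether equal replicate numbers pair the libraries was checked with the correlation of their deviations from the group means. Over 24 comparisons and 69 pairs this ranged from -0.386 to 0.231, and every pair was above 0.1 in 1 comparison, Mix against BPA in the male kidney, where all 3 pairs correlated best with their own number (0.112 to 0.222). The labels do not say what a replicate number stands for. Paired values are given beside that result.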

Results

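The 3′ ends of messenger RNA were counted in liver, kidney, thyroid, testis and ovary of Sprague-Dawley rats, an outbred laboratory strain, at postnatal day 63. Dams were given vehicle, bisphenol A (BPA) or a mixture of bisphenols (Mix) starting on day 6 of gestation and ending on day 6 of lactation, and their pups were dosed from postnatal day 7 to day 63. The total dose was equal in both treated groups, 500 mg/kg/day in dams and 250 mg/kg/day in pups. The dams' mixture held 160 mg/kg/day of BPA, 160 mg/kg/day of bisphenol F (BPF) and 180 mg/kg/day of bisphenol S (BPS). In BPA an isopropylidene bridge joins the phenol rings, in BPF a methylene bridge and in BPS a sulfonyl bridge. No group given BPF or BPS alone was analysed here. The 70 libraries came from 3 rats per organ, sex and treatment, except that female kidney had 2 vehicle, 2 BPA and 3 Mix libraries. Total counts per library lay between 4803807 and 10929957 over 17048 gene rows. The Y-linked gene Eif2s3y gave 8.75 to 47.1 CPM (counts scaled to library size) in male libraries and at most 2.42 CPM in female ones. Litter, cycle stage and time of collection were not given in the labels. Each dam kept 3 pups of each sex, so rats of a group may share a litter. All tests count each rat as independent, and a difference between litters cannot be told apart from a treatment effect.

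Ribosomal RNA rows took very different shares of the counts. In the male kidney they took 2.58% ± 0.898 (SD, n = 3) in vehicle rats, 30.2% ± 11.9 in BPA rats and 9.22% ± 9.78 in Mix rats (exact permutation p = 0.1 for BPA against vehicle, two-sided, the smallest that 3 rats against 3 allow). In the female thyroid the share was 1.63% ± 1.42 in vehicle, 4.89% ± 2.76 in BPA and 17.3% ± 6.07 in Mix. In the ovary it was 24.6% ± 4.39 in vehicle, 16.7% ± 3.70 in BPA and 21.5% ± 2.63 in Mix. Testis transcripts were read in other organs. Tnp1, a spermatid nuclear protein singled out after its values were seen, gave 33500 to 54500 CPM in testis libraries. In the male kidney it gave 220 to 404 CPM in vehicle, 30.5 to 143 CPM in BPA and 751 to 1460 CPM in Mix rats, against at most 24.9 CPM in the female kidney. BPA replicate 1 of the male thyroid reached 9910 CPM, and the female thyroid vehicle libraries ranged from 0.126 to 2930 CPM. Alb, the albumin transcript, was chosen after its values were seen and gave 47200 to 117000 CPM in the liver. It gave 51.5 to 2800 CPM in female thyroid vehicle libraries, against at most 98.5 in treated ones. Male thyroid vehicle replicate 3 had 1070 CPM of Alb, against at most 85.3 in the other male thyroid libraries. Ovaries had 1.88 to 194 CPM of Alb in vehicle and at most 64.4 in treated rats. In the ovary Tnp1 ranged from 0.433 to 440 CPM in vehicle libraries, against at most 46.2 in BPA and 23.2 in Mix. Of the 542 genes falling in the ovary of Mix rats 25 were testis-enriched, as were 4 of the 449 rising ones and 1088 of all 17048 rows. Testis-enriched rows, defined against the female kidney, took 1.85% to 2.56% of the counts in vehicle ovaries and 2.61% to 3.04% in Mix ovaries.

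**Figure D1:**
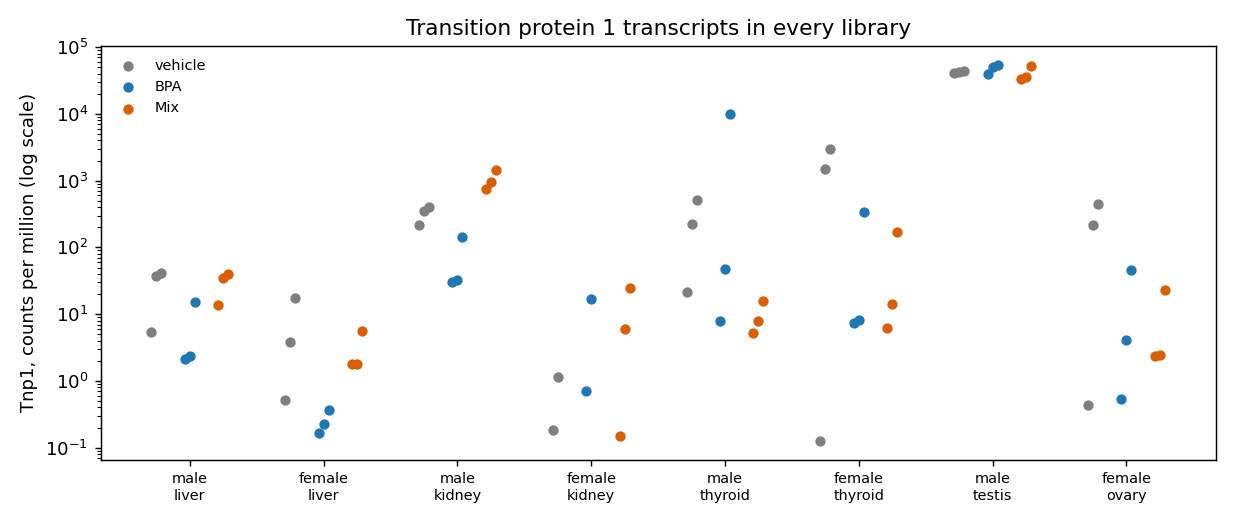
Tnp1 in CPM, on a log axis, in each library of every organ and sex, testis included, by treatment group; points are libraries. The male kidney Mix libraries lie between 751 and 1460 and the BPA libraries between 30.5 and 143.

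The number of genes that passed edgeR's quasi-likelihood test at an adjusted p below 0.05 ran from 0 to 991 per comparison. The largest counts belonged to the ovary against vehicle and to Mix against BPA in the male kidney. Of 534 tests of gene lists, 118 passed with camera's preset correlation of 0.01, and 1 of these, granulosa cell markers in the ovary of Mix against BPA rats, also passed with an estimated correlation. Other groupings of the same libraries passed up to 10 lists, and in 3 of 21 comparisons the treatment grouping passed more lists than any of them. In the paragraphs that follow, levels are CPM ± SD with n = 3 per group, log2 fold changes carry their SE, and adjusted p-values of genes are from edgeR and those of lists from camera.

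**Figure D2:**
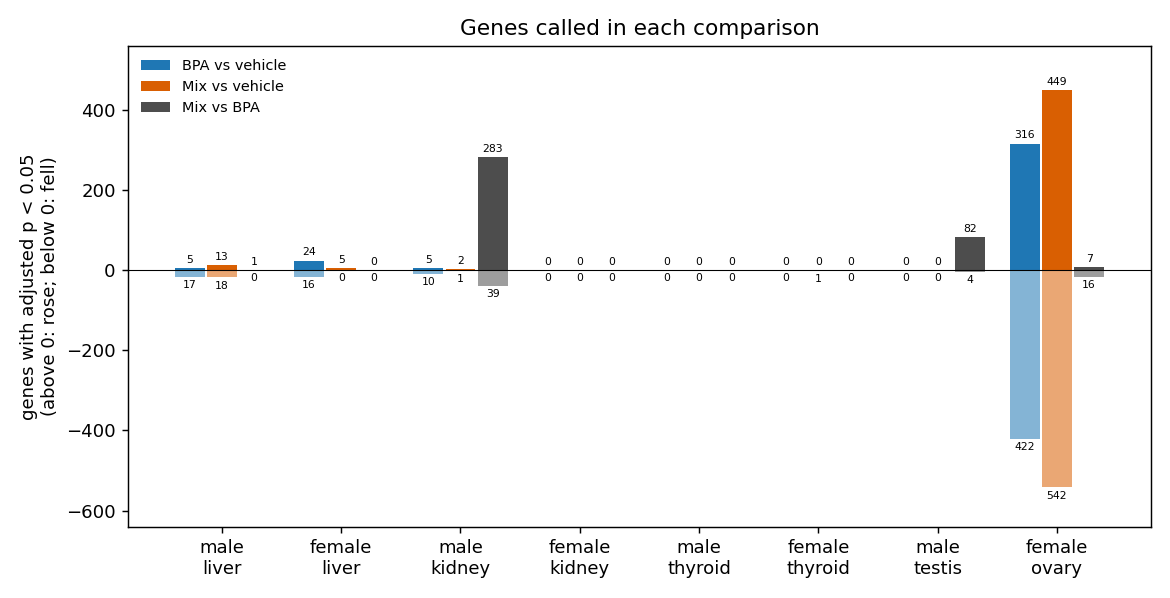
Number of genes with an edgeR adjusted p below 0.05 in each comparison, rising and falling, for each organ and sex. The ovary had 738 such genes in BPA and 991 in Mix against vehicle.

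In the male liver of BPA rats, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell to 0.0727 of the vehicle level, from 120 ± 43.8 to 8.78 ± 3.25 CPM (adjusted p = 0.00805). Abcg8, part of the sterol exporter of the bile canaliculus, fell from 19.8 ± 7.45 to 2.43 ± 0.265 CPM (adjusted p = 0.00311), and Nr0b2, a nuclear receptor that represses Cyp7a1, fell to 0.321 of vehicle (adjusted p = 0.0177). Bcl6, a transcriptional repressor, fell by 3.34 ± 0.49 on the log2 scale, and the macrophage receptor Marco fell by 2.01 ± 0.26. The plasma acute phase protein Orm1 rose 6.14-fold, from 1370 ± 297 to 8430 ± 1390 CPM (adjusted p = 0.00311), and the hepatocyte transcription factor Onecut1 rose 4.73-fold. Among 13 measured genes of bile acid synthesis and transport, 2 fell over all genes tested, and 2 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.655). Of 23 genes of cholesterol synthesis, 1 fell, Insig1, which restrains sterol synthesis, and 4 fell adjusted over the list alone (adjusted p = 0.000701; adjusted p = 0.489 with an estimated correlation). None of 7 erythroid markers passed over all genes and 5 rose adjusted over the list alone (adjusted p = 6.95e-07; adjusted p = 0.301 with an estimated correlation). In all, 5 genes rose and 17 fell among 9669 tested; DESeq2 called 65. The count of 22 became 9, 7 and 41 without vehicle replicate 1, 2 or 3, and 7, 3 and 7 without BPA replicate 1, 2 or 3; of 15 named genes, Abcg8, Onecut1 and Orm1 passed whichever library was left out.

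In the male liver of Mix rats, Zbtb16, a zinc finger repressor, fell from 25.2 ± 8.71 to 0.883 ± 0.334 CPM (adjusted p = 0.000599), and the deubiquitinase Usp2 fell by 3.46 ± 0.36 on the log2 scale (adjusted p = 0.000599). Tsc22d3, a glucocorticoid-induced gene also called Gilz, fell by 2.47 ± 0.27, Mfsd2a, a transporter of lysophospholipids, by 2.69 ± 0.34, and Bcl6 by 3.77 ± 0.50. Nr1d1, the clock repressor REV-ERBα, rose 9.55-fold, from 2.08 ± 1.10 to 20.1 ± 1.65 CPM (adjusted p = 0.00872), and Orm1 rose 3.83-fold. Of 9 circadian clock genes, 1 rose over all genes, and 3 rose and 2 fell adjusted over the list alone; the list's median was -0.29, its mean 0.15 and its test direction up (adjusted p = 0.915). Insig1 was again the 1 gene of 23 in cholesterol synthesis that fell, with 3 falling adjusted over the list alone (adjusted p = 2.95e-05; adjusted p = 0.541 with an estimated correlation). Of 12 macrophage markers 11 had a negative value, with 1 lower adjusted over the list alone and 0 over all genes (adjusted p = 0.00549; adjusted p = 0.505 with an estimated correlation). On the first principal component of the male liver, Mix replicate 1 lay at 60.4 and the other libraries between -22.9 and -0.48. The count was 31, with 13 rising and 18 falling, against 95 by DESeq2, and 31 without Mix replicate 1. It was 18, 10 and 57 without vehicle replicate 1, 2 or 3, and Bcl6, Mfsd2a, Tsc22d3, Usp2, Zbtb16 and Zfp354a passed whichever library was left out.

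Set directly against BPA rats, male livers of Mix rats differed in 1 gene: Hsd17b2, which oxidises estradiol and testosterone, was 3.31-fold higher (144 ± 34.5 against 43.4 ± 8.47 CPM; adjusted p = 0.02). For Orm1 the Mix minus BPA difference was -0.68 log2 (95% interval -1.29 to -0.08, not adjusted for the number of genes), for Bcl6 -0.43 (-1.57 to 0.71) and for Insig1 0.02 (-0.69 to 0.74). Nr1d1 was 2.67 higher in Mix rats (1.62 to 3.72) with an adjusted p of 0.0819. Of 24 genes named against vehicle, 8 had an interval that included 0, and for 2 the interval lay within 1 log2 unit of 0. Of 16 genes of ER stress and amino acid response, 6 rose adjusted over the list alone and 0 over all genes (adjusted p = 1.2e-07; adjusted p = 0.242 with an estimated correlation). At an unadjusted p below 0.05 there were 598 genes, and DESeq2 called 48. The count was 6 and 4 without vehicle replicate 1 or 3, 0, 0 and 3 without BPA replicate 1, 2 or 3, and 0, 4 and 5 without Mix replicate 1, 2 or 3; adding the replicate number or the ribosomal RNA share to the model gave 2.

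In the female liver of BPA rats, Inmt, a methyltransferase of indole amines, rose 46.4-fold, from 0.726 ± 0.136 to 34.6 ± 18.5 CPM (adjusted p = 0.000229), and Rbp7, a retinol carrier, rose 25.3-fold (adjusted p = 0.00368). Nr0b2 rose 3.65-fold, from 7.64 ± 0.723 to 27.9 ± 6.87 CPM (adjusted p = 0.00446), and Hsd11b1, which regenerates active glucocorticoid, rose 6.10-fold. A1bg, a plasma protein of female rat liver, fell from 2060 ± 321 to 258 ± 44.0 CPM (adjusted p = 0.0141), Lifr, a cytokine receptor, fell by 1.87 ± 0.28 on the log2 scale, and Krt23, a keratin, fell by 3.45 ± 0.50. Of 11 female-biased liver genes 1 fell, and 7 fell adjusted over the list alone (adjusted p = 5.81e-09; adjusted p = 0.0804 with an estimated correlation). Of 8 male-biased liver genes 3 fell adjusted over the list alone and 0 over all genes (adjusted p = 0.00313; adjusted p = 0.405 with an estimated correlation). The 189 genes higher in female than male livers of Mix rats had a median log2 value of -0.18 (adjusted p = 0.0605; adjusted p = 0.714 with an estimated correlation). None of 28 PPARα targets passed over all genes and 3 fell adjusted over the list alone (adjusted p = 0.000948; adjusted p = 0.405 with an estimated correlation). All 6 erythroid markers had a positive value, with 0 past the threshold over all genes or the list alone (adjusted p = 0.0123; adjusted p = 0.405 with an estimated correlation). Altogether 24 genes rose and 16 fell among 9554, and DESeq2 called 185. The edgeR count was 19 with the replicate number in the model, 21 with the ribosomal RNA share and 229 without the low-count filter. Leaving out vehicle replicate 1, 2 or 3 gave 11, 8 and 23 genes, BPA replicate 1 gave 16, and Mix replicate 1, 2 or 3 gave 22, 17 and 18; Inmt, Krt23, Lifr, Nr0b2 and Rbp7 passed each time.

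In the female liver of Mix rats the 5 genes that passed all rose: Lppr3, Rbp7, Inmt, Nr0b2 and Pfkfb1, a bifunctional regulator of glycolysis. Nr0b2 rose 3.89-fold to 29.8 ± 4.15 CPM (adjusted p = 0.0061), Rbp7 22.1-fold (adjusted p = 0.0061) and Inmt 9.31-fold to 6.92 ± 1.67 CPM (adjusted p = 0.0382). Of 23 cholesterol synthesis genes none passed over all genes and 3 fell adjusted over the list alone (adjusted p = 5.24e-07; adjusted p = 0.303 with an estimated correlation). Against 5 in edgeR, DESeq2 called 56. The count was 2 and 0 without vehicle replicate 1 or 2, 11 without BPA replicate 3 and 3 without Mix replicate 1, and none of these genes passed with every library left out in turn.

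Between Mix and BPA rats, the female liver gave 0 genes by edgeR, with 621 at an unadjusted p below 0.05 and 34 by DESeq2. Lifr had a log2 value of 1.77 ± 0.27 and Gpnmb, a macrophage glycoprotein, -1.76 ± 0.26 (adjusted p = 0.0612 for each). The difference in Rbp7 was -0.20 (95% interval -1.10 to 0.71), in Nr0b2 0.09 (-0.40 to 0.58) and in Inmt -2.32 (-3.16 to -1.47, adjusted p = 0.0853). None of 12 macrophage markers passed over all genes and 5 fell adjusted over the list alone (adjusted p = 1.4e-06; adjusted p = 0.125 with an estimated correlation). Without vehicle replicate 2 or 3 the count was 2 and 7, without BPA replicate 2 or 3 it was 1 and 4, and the replicate number in the model gave 5.

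In the male kidney of BPA rats, Dcn, the matrix proteoglycan decorin, rose 3.68-fold, from 132 ± 10.7 to 486 ± 31.0 CPM (adjusted p = 0.00358). Tcf21, a transcription factor of stromal cells, rose 3.11-fold and Pdgfra, a growth factor receptor of fibroblasts, 1.93-fold. Phgdh, the first enzyme of serine synthesis, fell to 0.272 of vehicle, and Apcs, the serum amyloid P component, to 0.220. Fhl4, Pgk2 and Prm1, all transcribed in male germ cells, fell by 3.94 ± 0.61 log2 units, to 0.0826 of the vehicle level and by 2.26 ± 0.34 log2 units (adjusted p = 0.0428, 0.0426 and 0.0428), and 7 of the 10 falling genes were testis-enriched. Of 11 extracellular matrix genes 1 rose over all genes and 9 rose adjusted over the list alone (adjusted p = 1.08e-10; adjusted p = 0.128 with an estimated correlation), in libraries with a ribosomal RNA share of 30.2% against 2.58% in vehicle. Of 7 erythroid markers 2 rose adjusted over the list alone and 0 over all genes (adjusted p = 0.00986; adjusted p = 0.637 with an estimated correlation). The adipocyte gene Fabp4 had a log2 value of 1.93 ± 0.48 (adjusted p = 0.0841). Among 19 proximal tubule markers none passed over all genes, and 9 fell and 1 rose adjusted over the list alone (adjusted p = 0.00122; adjusted p = 0.637 with an estimated correlation). In total 5 genes rose and 10 fell among 11000. DESeq2 called 822, and edgeR called 1 without testis-enriched rows, 1 with the ribosomal RNA share in the model and 168 with the replicate number. The count was 0, 8 and 0 without vehicle replicate 1, 2 or 3, 28, 1 and 1 without BPA replicate 1, 2 or 3, and 886, 481 and 3 without Mix replicate 1, 2 or 3, and no named gene passed in all of these fits.

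In the male kidney of Mix rats, Dbp, an output transcription factor of the circadian clock, rose 4.55-fold, from 30.2 ± 3.11 to 137 ± 19.1 CPM (adjusted p = 0.000331), and Nr1d1 rose 4.46-fold, from 11.1 ± 1.79 to 49.7 ± 9.29 CPM (adjusted p = 0.00814). Over all genes 2 of 9 circadian clock genes rose, and 4 rose and 2 fell adjusted over the list alone; the list's median was -0.28, its mean 0.15 and its test direction up (adjusted p = 0.0688). None of 11 extracellular matrix genes passed over all genes and 1 rose adjusted over the list alone (adjusted p = 0.679). There were 2 rising genes and 1 falling gene, against 97 by DESeq2. Without vehicle replicate 3 the count was 5, without BPA replicate 3 it was 5, and without Mix replicate 1, 2 or 3 it was 7, 19 and 5; the ribosomal RNA share in the model gave 5 and the replicate number 26, and Dbp passed whichever library was left out.

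**Figure D3:**
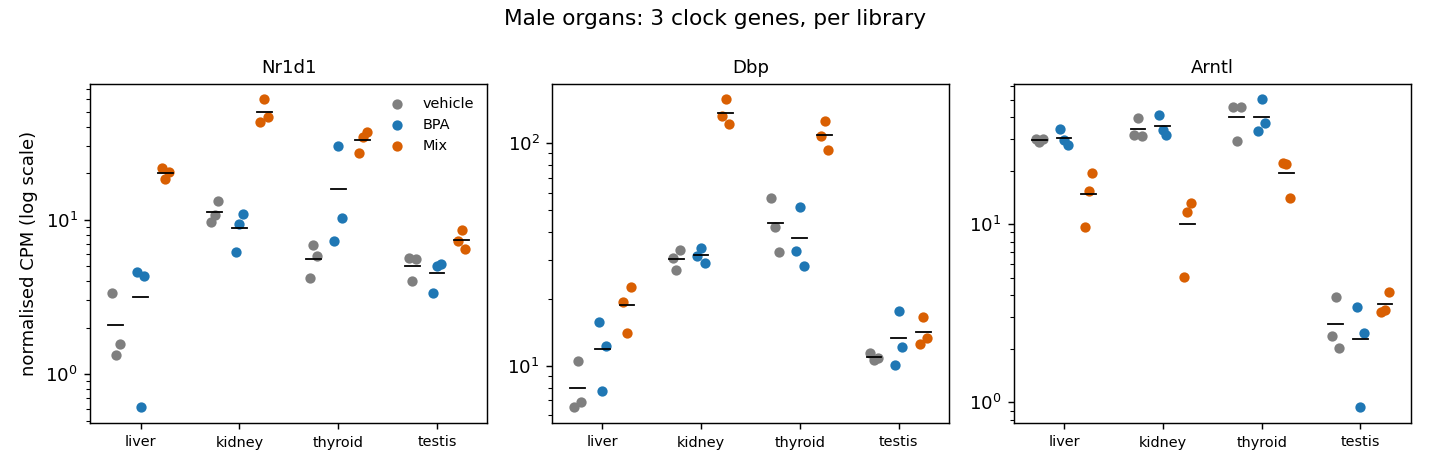
Levels of Nr1d1, Dbp and Arntl in CPM, on a log axis, in each library of the male liver, kidney, thyroid and testis, by treatment group; points are libraries and lines are means. In Mix against vehicle rats Dbp was 2.19 log2 units higher in the kidney and Nr1d1 3.26 higher in the liver.

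Mix and BPA rats differed in 322 genes of the male kidney, 283 higher and 39 lower in Mix. Of the 283, 225 were testis-enriched, among them Fhl4, 33.6-fold higher (adjusted p = 0.00322), and Pgk2, 27.4-fold higher (adjusted p = 0.00142). The clock genes Dbp, Nr1d1 and Nr1d2 were 4.37-fold, 5.61-fold and 2.95-fold higher, and Arntl, the clock activator BMAL1, was lower by 1.81 ± 0.30 log2 units (9.99 ± 4.31 against 35.7 ± 4.99 CPM; adjusted p = 0.0117). Of 9 clock genes 3 rose and 1 fell, and 4 rose and 2 fell adjusted over the list alone; the median was -0.22, the mean 0.30 and the test direction up (adjusted p = 0.0256; adjusted p = 0.509 with an estimated correlation). Col3a1, Col1a2, Col1a1 and Dcn were the 4 of 11 extracellular matrix genes that were lower, Col3a1 at 47.8 ± 8.08 against 168 ± 47.3 CPM, and 5 were lower adjusted over the list alone (adjusted p = 1.13e-09; adjusted p = 0.191 with an estimated correlation). The ribosomal RNA share was 9.22% in Mix and 30.2% in BPA libraries. All 7 erythroid markers were lower, 5 of them adjusted over the list alone and 0 over all genes (adjusted p = 0.000347; adjusted p = 0.509 with an estimated correlation). Of 8 loop of Henle and distal tubule markers 2 were lower adjusted over the list alone and 0 over all genes (adjusted p = 0.0256; adjusted p = 0.509 with an estimated correlation). Among 19 proximal tubule markers 4 were higher, including the glucose transporter Slc5a2 at 3.31-fold, and 7 adjusted over the list alone (adjusted p = 0.0176; adjusted p = 0.535 with an estimated correlation). Of 27 PPARα targets 3 were higher, Acaa1b, Acaa2 and Cyp4a1, and 6 adjusted over the list alone (adjusted p = 0.0256; adjusted p = 0.535 with an estimated correlation). Each of the 14 genes named against vehicle had a Mix minus BPA interval that excluded 0. These genes were chosen in the same BPA or Mix libraries, which favours such intervals. Fhl4, Pgk2 and Prm1, transcribed in male germ cells, are among them. Without testis-enriched rows 8 genes passed, DESeq2 called 714, and with replicate numbers as a block 414 passed while Cyp4a1 and the PPARα and clock lists no longer did. The count was 213 and 181 without vehicle replicate 1 or 3, 20 and 41 without BPA replicate 2 or 3, and 653 without Mix replicate 1; Col3a1, Dbp, Fhl4, Nr1d1 and Pgk2 passed each time.

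In the female kidney no gene passed in any comparison by edgeR, with 2 vehicle, 2 BPA and 3 Mix rats. Against vehicle, Syne4, a nuclear envelope protein, had a log2 value of 2.88 ± 0.42 in BPA rats (109 ± 16.5 against 15 ± 4.90 CPM, n = 2 each; edgeR adjusted p = 0.151). In Mix rats Cyr61, a matricellular protein, had -1.59 ± 0.21 (adjusted p = 0.203) and Tcf21 -1.71 ± 0.28 (adjusted p = 0.302). Between Mix and BPA rats, Nudt16 had -1.27 ± 0.21 (adjusted p = 0.683). Of 24 oxidative phosphorylation genes 5 rose in BPA rats adjusted over the list alone and 0 over all genes (adjusted p = 0.000689; adjusted p = 0.888 with an estimated correlation). In the same rats 2 of 7 erythroid markers rose adjusted over the list alone and 0 over all genes (adjusted p = 0.0244; adjusted p = 0.888 with an estimated correlation). Hba1 stood at 8230 ± 2540 against 3850 ± 940 CPM. The 8 loop of Henle and distal tubule markers had a mean log2 value of -0.72, with 0 past the threshold (adjusted p = 0.0249; adjusted p = 0.888 with an estimated correlation). Without vehicle replicate 2 that direction reversed. Of 12 immediate early and heat shock genes 3 fell in Mix rats adjusted over the list alone and 0 over all genes (adjusted p = 0.00245; adjusted p = 0.738 with an estimated correlation). For BPA, Mix and Mix against BPA, 1754, 1111 and 779 genes had an unadjusted p below 0.05, and DESeq2 called 314, 68 and 12; with the ribosomal RNA share in the model edgeR called 994, 403 and 1. Without vehicle replicate 1 the counts were 806, 329 and 1; without vehicle replicate 2, Mix against vehicle and Mix against BPA gave 1 each, and without BPA replicate 2, BPA against vehicle and Mix against BPA gave 1 each.

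In the male thyroid no gene passed by edgeR in any comparison. The smallest p-values belonged to Cpa6, a carboxypeptidase, in BPA rats (-2.42 ± 0.33; adjusted p = 0.436), to Fkbp5, a glucocorticoid-induced cochaperone, in Mix rats (-1.85 ± 0.26; adjusted p = 0.458) and to Aplnr, the apelin receptor, between Mix and BPA rats (1.79 ± 0.30; adjusted p = 0.304). Calca, which encodes calcitonin in C cells, stood at 6230 ± 615 CPM in vehicle, 11700 ± 991 in BPA and 12200 ± 2370 in Mix rats, and 2 of 6 C cell markers rose in BPA rats adjusted over the list alone, 0 over all genes (adjusted p = 0.000416; adjusted p = 0.0865 with an estimated correlation). Of 8 adipocyte markers 4 fell in Mix rats adjusted over the list alone and 0 over all genes (adjusted p = 3.86e-09; adjusted p = 0.142 with an estimated correlation). Thyroglobulin (Tg) stood at 84500 ± 17400 CPM in vehicle, 50900 ± 12900 in BPA and 71100 ± 9940 in Mix rats. The BPA libraries include replicate 1, where testis-enriched rows took 14.8% of the counts. None of 15 follicular cell markers passed over all genes. For BPA, Mix and Mix against BPA, 915, 551 and 1533 genes had an unadjusted p below 0.05 and DESeq2 called 16, 35 and 114.

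In the female thyroid of Mix rats 1 gene passed: Rbp4, the plasma retinol carrier, which adipocytes also express, fell to 0.139 of vehicle, from 146 ± 7.70 to 20.3 ± 7.54 CPM (adjusted p = 0.0231). In BPA rats Rbp4 stood at 28.1 ± 5.19 CPM (log2 -2.38 ± 0.29; adjusted p = 0.0548). Markers of neighbouring tissue varied between libraries: the muscle actin Acta1 gave 799 ± 1010 CPM in vehicle, 32.9 ± 29.7 in BPA and 554 ± 946 in Mix rats, and the adipocyte gene Fabp4 2280 ± 2210, 575 ± 303 and 508 ± 405. Of 8 adipocyte markers 2 fell in BPA rats adjusted over the list alone and 0 over all genes (adjusted p = 0.00066; adjusted p = 0.704 with an estimated correlation), and 2 in Mix rats (adjusted p = 0.0157; adjusted p = 0.931 with an estimated correlation). Of 24 oxidative phosphorylation genes 6 fell in Mix rats adjusted over the list alone and 0 over all genes (adjusted p = 1.93e-05; adjusted p = 0.931 with an estimated correlation). Between Mix and BPA rats, Tmprss3 had the smallest p (-2.45 ± 0.37; adjusted p = 0.447). edgeR called 0, 1 and 0 genes for BPA, Mix and Mix against BPA, where 1485, 2561 and 650 had an unadjusted p below 0.05 and DESeq2 called 223, 1386 and 40. Without vehicle replicate 1 the BPA and Mix counts were 1119 and 2093 and without vehicle replicate 3 they were 55 and 108. The BPA count was 1 without Mix replicate 2, the Mix count was 75 without BPA replicate 2, and Rbp4 was lost in Mix rats, for a count of 0, without vehicle replicate 2, BPA replicate 1 or 3, or Mix replicate 1 or 3, and with the ribosomal RNA share in the model.

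In the testis no gene passed against vehicle by edgeR. The smallest p-values were those of Ncor1, a nuclear receptor corepressor, in BPA rats (-0.69 ± 0.12; adjusted p = 0.225) and of Pdilt, a testis chaperone, in Mix rats (1.05 ± 0.17; adjusted p = 0.227). Kap, an abundant androgen-regulated kidney transcript, gave 7.33 ± 5.55 CPM in Mix and 0.154 ± 0.181 in vehicle testis (adjusted p = 0.227). None of 12 spermatid markers, 16 Sertoli cell markers or 13 Leydig cell and steroidogenesis genes passed over all genes in any comparison. In BPA and Mix rats 1337 and 591 genes had an unadjusted p below 0.05 and DESeq2 called 104 and 19. Without BPA replicate 1 the BPA count was 420, without Mix replicate 1 it was 12, and without Mix replicate 3 it was 1; without vehicle replicate 3 both counts were 1.

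Between Mix and BPA testes, Apc, a regulator of Wnt signalling, was 2.71-fold higher in Mix rats (adjusted p = 0.0249) and Lman1, a cargo receptor of the secretory pathway, 2.48-fold higher (adjusted p = 0.0239). The proliferation genes Mki67, Top2a and Cenpf were 2.14-fold, 1.91-fold and 1.89-fold higher, and Gstp1, a glutathione transferase, stood at 21.2 ± 1.71 against 43.7 ± 9.41 CPM (adjusted p = 0.0277). Mki67, Top2a and Cenpf were the 3 of 28 cell cycle genes that rose, over all genes and adjusted over the list alone (adjusted p = 0.446). The count was 86, with 82 higher and 4 lower, and DESeq2 called 447. It was 26, 14 and 0 without vehicle replicate 1, 2 or 3, 994, 0 and 0 without BPA replicate 1, 2 or 3, and 432, 1 and 1 without Mix replicate 1, 2 or 3, so that no named gene passed in all of these fits; it was 0 with the replicate number and 546 with the ribosomal RNA share in the model.

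In the ovary of BPA rats, Cyp17a1, the enzyme that makes androgens in theca cells, rose 39.5-fold, from 3.35 ± 1.68 to 135 ± 81.9 CPM (adjusted p = 0.000437). Lhcgr, the receptor for luteinising hormone, rose 12.3-fold, from 2.94 ± 1.79 to 36.9 ± 12.7 CPM (adjusted p = 0.00141), while Star, which carries cholesterol into mitochondria, fell from a mean of 1500 (1380 to 1720) to 802 (663 to 907) CPM (adjusted p = 0.0137). Of 12 granulosa cell markers 4 rose: Amh, from 13.5 ± 1.27 to 37.7 ± 3.87 CPM, and Fshr, Inhba and Cyp19a1, by 1.58 ± 0.31, 1.45 ± 0.36 and 1.60 ± 0.41 on the log2 scale; 7 rose adjusted over the list alone (adjusted p = 9.26e-05; adjusted p = 0.0753 with an estimated correlation). Of 11 CAR and PXR targets, genes induced by foreign compounds, 4 rose and 1 fell, and 5 rose and 2 fell adjusted over the list alone; Ephx1 rose 4.37-fold, Gsta2 7.35-fold and Aldh1a1 3.68-fold. That list had a median of 0.51, a mean of -0.09 and an upward test (adjusted p = 0.00146; adjusted p = 0.213 with an estimated correlation). Of 24 oxidative phosphorylation genes 3 fell, the complex I subunit Ndufa2 to 0.524 of vehicle, and 9 fell adjusted over the list alone (adjusted p = 9.26e-05; adjusted p = 0.608 with an estimated correlation). Of 16 ER stress genes 1 fell, Sdf2l1, and 5 adjusted over the list alone (adjusted p = 9.26e-05; adjusted p = 0.587 with an estimated correlation); of 10 macrophage markers 3 fell, Aif1 to 0.360 of vehicle, and 5 adjusted over the list alone (adjusted p = 0.00127; adjusted p = 0.254 with an estimated correlation). Of 15 extracellular matrix genes 3 fell, Timp1, Mmp2 and Tnc, over all genes and adjusted over the list alone (adjusted p = 0.623). In all 316 genes rose and 422 fell among 10871, and DESeq2 called 1163. The count was 255 and 440 without vehicle replicate 2 or 3, 184 and 216 without BPA replicate 2 or 3, and 96 with the ribosomal RNA share in the model; of 40 named genes 23 passed whichever library was left out, Cyp17a1, Lhcgr, Amh and Ephx1 among them.

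**Figure D4:**
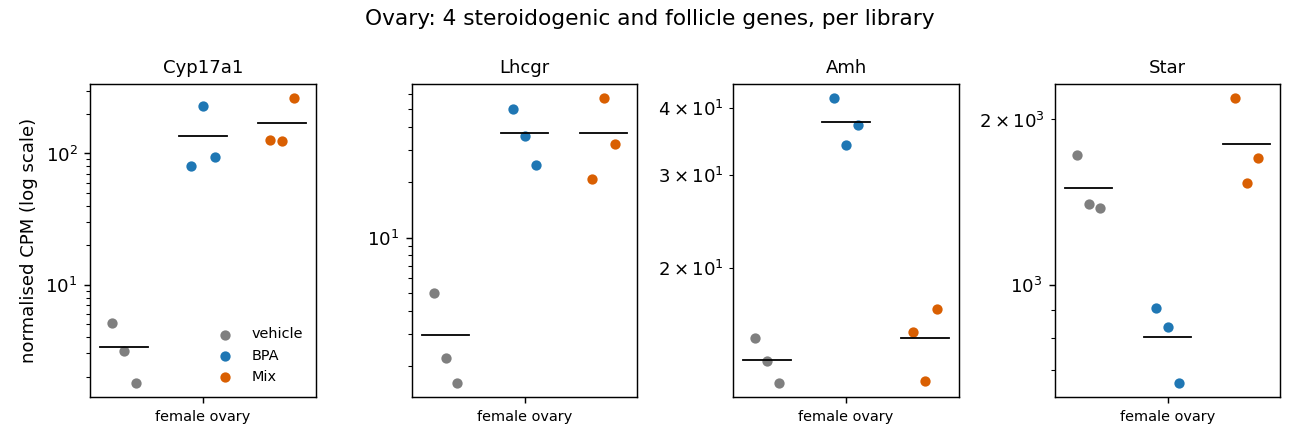
CPM, on a log axis, of Cyp17a1, Lhcgr, Amh and Star in each ovary library by treatment group; points are libraries and lines are means. Mean Cyp17a1 was 3.35 in vehicle, 135 in BPA and 172 in Mix rats.

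In the ovary of Mix rats, Cyp17a1 rose 50.5-fold to 172 ± 81.0 CPM (adjusted p = 0.000306) and Lhcgr 12.3-fold to 36.8 ± 18.7 CPM (adjusted p = 0.00144). Cyp19a1, the aromatase of granulosa cells, rose 4.69-fold, Prlr, the prolactin receptor, 2.41-fold, and Srd5a1, a steroid 5α-reductase, fell to 0.317 of vehicle. Of 22 cholesterol synthesis genes 6 rose, Hsd17b7 5.68-fold, Msmo1 2.35-fold and Hmgcs1 2.03-fold among them, and 9 rose adjusted over the list alone (adjusted p = 4.94e-06; adjusted p = 0.417 with an estimated correlation). Of 10 steroidogenesis and theca markers 2 rose and 1 fell, and 5 rose and 1 fell adjusted over the list alone (adjusted p = 0.00495; adjusted p = 0.417 with an estimated correlation). Of 11 CAR and PXR targets 4 rose and 1 fell, and 5 rose and 1 fell adjusted over the list alone, Gsta2 6.69-fold and Ephx1 4.04-fold higher (adjusted p = 0.000913; adjusted p = 0.224 with an estimated correlation). Oxidative phosphorylation had 8 of 24 genes lower, and 10 adjusted over the list alone (adjusted p = 0.000319; adjusted p = 0.486 with an estimated correlation). ER stress had 5 of 16 lower, Sdf2l1 at 0.305 of vehicle, and 7 adjusted over the list alone (adjusted p = 2.96e-05; adjusted p = 0.417 with an estimated correlation). The count was 991, with 449 rising and 542 falling. It was 275 without vehicle replicate 2, 263 and 351 without Mix replicate 1 or 3, and 616 with the ribosomal RNA share in the model; of 52 named genes 25 passed whichever library was left out, Cyp17a1, Lhcgr, Cyp19a1 and Hsd17b7 among them.

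Between Mix and BPA ovaries, Amh, the granulosa hormone that restrains follicle recruitment, was lower in Mix rats at 14.7 ± 2.28 against 37.7 ± 3.87 CPM (adjusted p = 0.0176), and its receptor Amhr2 was lower at 28.6 ± 5.19 against 76.3 ± 10.3 CPM (adjusted p = 0.0176). Star was 2.25-fold higher (1530 to 2190 against 663 to 907 CPM; adjusted p = 0.0272), Scgb1a1, a secreted uteroglobin, 3.37-fold and Sncg, a synuclein, 2.93-fold. Of 12 granulosa cell markers 1 was lower over all genes and 7 adjusted over the list alone (adjusted p = 2.51e-10; adjusted p = 0.00895 with an estimated correlation). None of 22 cholesterol synthesis genes passed over all genes and 13 were higher adjusted over the list alone (adjusted p = 1.93e-13; adjusted p = 0.288 with an estimated correlation). The Mix minus BPA difference was 0.36 log2 for Cyp17a1 (95% interval -0.49 to 1.20), -0.01 for Lhcgr (-0.83 to 0.81) and -0.11 for Ephx1 (-0.60 to 0.37). Of 66 genes named against vehicle, 40 had an interval that included 0, and for 35 the interval lay within 1 log2 unit of 0. Cycle stages were not given, so a difference in stage between Mix and BPA rats cannot be told apart from one between the treatments. There were 7 higher and 16 lower genes, against 280 by DESeq2. The count of 23 was 15 without vehicle replicate 1, 2 and 1 without BPA replicate 2 or 3, 0 and 38 without Mix replicate 1 or 2, and 11 with the ribosomal RNA share in the model, and no named gene passed in all of these fits.

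BPA and Mix calls against vehicle overlapped in the ovary, where 409 genes passed in both, 150 rising and 259 falling, with 0 in opposite directions. Independent lists of these sizes would share 13.1 rising and 21 falling genes. In 20 simulations without any change, where both comparisons used the same simulated vehicle libraries, 0 were shared on average. Across genes, which are not independent replicates, the ovary log2 fold changes had r = 0.771 against 0.502 simulated and a covariance of 0.458 against 0.0964. The male liver shared 10 genes, 2 rising (Orm1 and Slc25a30) and 8 falling, among them Bcl6, Abcg8, Insig1 and Zbtb16, where independent lists would share 0.00672 and 0.0316 and simulations 0.1; r was 0.487 against 0.483 simulated and the covariance 0.118 against 0.0770. The female liver shared 5 rising genes, Inmt, Lppr3, Nr0b2, Pfkfb1 and Rbp7, against 0.0126 for independent lists, with a covariance of 0.207 against 0.0958. In the male thyroid r was -0.240 against 0.505 simulated, in the male kidney 0.173 against 0.480 and in the testis 0.271 against 0.480. It was 0.695 against 0.553 in the female kidney and 0.806 against 0.497 in the female thyroid. Testis-enriched rows took 14.8% of the counts in BPA replicate 1 of the male thyroid. In the male kidney they took 0.287% to 0.425% in BPA and 1.06% to 1.7% in Mix libraries. How far these rows moved r was not tested. The 3 vehicle libraries could not be divided into sets of at least 2, so part of each excess may come from the shared controls. Without vehicle replicate 2 or 3 the ovary overlap was 110 and 258, without BPA replicate 2 or 3 it was 132 and 142, and without Mix replicate 1 or 3 it was 173 and 169. In the male liver it was 2, 0 and 26 without vehicle replicate 1, 2 or 3 and 4, 2 and 3 without BPA replicate 1, 2 or 3, and in the female liver 2 and 0 without vehicle replicate 1 or 2 and 3 without Mix replicate 1.

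Whether a treatment effect differed between the sexes was tested as an interaction. In the liver, Nr0b2 fell in BPA males and rose in BPA females, a male minus female difference of -3.51 ± 0.36 log2 units (edgeR adjusted p = 3.55e-05), and Onecut1 differed by 2.74 ± 0.41 and Mfsd2a by -2.94 ± 0.43. In Mix rats Usp2 differed by -4.00 ± 0.51 (adjusted p = 0.0013), Tsc22d3 by -2.50 ± 0.38 and Cdkn1a, the cell cycle inhibitor p21, by -3.26 ± 0.51. BPA gave 21 liver genes with a sex difference and Mix 19. In the kidney BPA gave 551: Tcf21 rose in males, with a log2 value of 1.64, and stood at -1.61 in females (difference 3.24 ± 0.39; adjusted p = 0.00285), and Pdgfra differed by 1.93 ± 0.31. Mix gave 1, Dbp, at 1.79 ± 0.25 (adjusted p = 0.0201). In the thyroid edgeR gave 0 for both, with 2045 and 1032 genes at an unadjusted p below 0.05 and 237 and 54 by DESeq2. Of 570 genes higher in male than in female Mix kidneys, the 543 tested in BPA males had a median of -1.06 (camera adjusted p = 4.27e-21; adjusted p = 0.236 with an estimated correlation); without testis-enriched rows the direction turned (adjusted p = 0.4593). The liver BPA count was 5, 8 and 69 without male vehicle replicate 1, 2 or 3, 6 and 10 without male BPA replicate 1 or 2, and 12 and 7 without female vehicle replicate 2 or 3. The liver Mix count was 9, 8 and 36 without male vehicle replicate 1, 2 or 3, 11, 12 and 11 without female vehicle replicate 1, 2 or 3, and 7 and 11 without female Mix replicate 1 or 3. The kidney BPA count was between 35 and 267 without male vehicle replicate 1, 2 or 3, 183 and 293 without male BPA replicate 1 or 2, 1259 and 946 without male Mix replicate 1 or 2, 1107 and 72 without female vehicle replicate 1 or 2, 104 and 2 without female BPA replicate 1 or 2, and 366 without female Mix replicate 1. It was 1, Tcf21, with the ribosomal RNA share in the model; that share was 2.58% in vehicle and 30.2% in BPA males, and 28.2% and 19.1% in females. The kidney Mix count was 65 without female vehicle replicate 1, 2 without male Mix replicate 1, and 0 without male vehicle replicate 1, 2 or 3, male Mix replicate 2, female vehicle replicate 2, or female Mix replicate 1 or 2, and 0 with the replicate number in the model. Without female vehicle replicate 1 the thyroid BPA and Mix counts were 725 and 396, and without male Mix replicate 3 the thyroid Mix count was 1.

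Across genes, male and female log2 fold changes had r = 0.0671 for BPA and 0.0521 for Mix in the liver, -0.265 and 0.0234 in the kidney, and -0.325 and 0.517 in the thyroid; genes are not independent replicates. The thyroid BPA value was 0.292 without male BPA replicate 1, the library with 9910 CPM of Tnp1. The thyroid Mix value was 0.348 without female vehicle replicate 1, a library with 2930 CPM of Tnp1. It was 0.3975 and 0.3942 without replicate 3 of the male vehicle or Mix rats. In the kidney the ribosomal RNA share was 2.58% in vehicle and 30.2% in BPA males, and 28.2% and 19.1% in females. Its part in the kidney BPA value was not tested. The liver BPA value was 0.131, 0.112 and -0.00887 without male vehicle replicate 1, 2 or 3, and 0.00570 and 0.111 without female vehicle replicate 1 or 3. The liver Mix value was 0.0875 without male vehicle replicate 1, 0.0119 and 0.133 without female vehicle replicate 1 or 3, and 0.0929 without female Mix replicate 3. The kidney BPA value was -0.146 and -0.173 without replicate 2 of the female vehicle or BPA rats, and the kidney Mix value 0.0727 without male vehicle replicate 1, 0.0795 without female vehicle replicate 2 and -0.0597 without female Mix replicate 2.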

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

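The counts over other groupings of the libraries and the test on the female thyroid were chosen after the results were seen. So were the sex differences with the ribosomal RNA share in the model and the clock values over 4 shared genes. For the other tests on the male kidney and on the clock genes, the bounds were set before these tests were run. The ribosomal RNA covariate and the testis-enriched rows were themselves added after the values were seen.

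Results in this part were picked because the treatment effect differed between male and female rats in an edgeR interaction test. BPA gave 21 such genes in the liver. Nr0b2 had a male minus female difference of -3.51 log2 units (adjusted p = 3.55e-05), with -1.64 in males and 1.87 in females. Mfsd2a had -2.94 (adjusted p = 0.00405), Onecut1 2.74 (adjusted p = 0.00415), Tsku -4.08 (adjusted p = 0.0122) and Inmt -5.84 (adjusted p = 0.0122), where Inmt stood at 65.8 ± 55.1 CPM in male vehicle and 0.706 ± 0.125 CPM in female vehicle livers. In 40 drawn groupings of the liver libraries, 1, the real one, gave as many genes, and the highest other gave 5. The groupings mixed treated and vehicle libraries in both sexes, so they stand for no treatment effect in either sex. They cannot decide whether chance gave a difference between the sexes. The count ran from 5 without male vehicle replicate 1 to 69 without male vehicle replicate 3, and 7 of 18 libraries moved it by over 1.5 times when left out; it was 13 with the ribosomal RNA share in the model.

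Mix gave 19 genes with a sex difference in the liver. Usp2 had -4.00 (adjusted p = 0.0013), Mfsd2a -3.16 (adjusted p = 0.00147), Nr0b2 -2.37 (adjusted p = 0.0035), Tsc22d3 -2.50 (adjusted p = 0.0035) and Cdkn1a -3.26 (adjusted p = 0.0045). Here too 1 of 40 groupings gave as many genes, the real one, with 10 in the highest other. For the same reason this cannot decide whether chance gave a difference between the sexes. The count ran from 7 without female Mix replicate 1 to 36 without male vehicle replicate 3, and 8 of 18 libraries moved it by over 1.5 times; it was 12 with the ribosomal RNA share in the model. In the thyroid edgeR called 0 genes for BPA (2045 at an unadjusted p below 0.05; DESeq2 237) and 0 for Mix (1032; DESeq2 54), and all 40 groupings gave as many, which a count of 0 fixes, so this says nothing about chance. The highest other gave 601 for BPA, which points to a structure of the thyroid samples apart from the treatment groups, and 0 for Mix.

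BPA gave 551 genes with a sex difference in the kidney, 12 of them testis-enriched. Tcf21 had 3.24 (adjusted p = 0.00285), Dmbt1 3.44, Pdgfra 1.93, Lrp1 2.43 and Apcs -3.77 (adjusted p = 0.0108 for each of these 4). The ribosomal RNA share rose with BPA in males (2.58% to 30.2%) and was lower in BPA females (19.1% against 28.2% in vehicle). With that share in the model 1 gene, Tcf21, had a sex difference (3.76; adjusted p = 0.0313); over the 551 genes the median difference, in the direction first seen, went from 1.60 to 1.41 and the median standard error from 0.371 to 0.537. The calls ended as the error grew and the difference shrank, so the ribosomal RNA share stays open as a source of these calls. With 2 female vehicle and 2 female BPA libraries no other groupings were counted. The count ran from 2 without female BPA replicate 2 to 1259 without male Mix replicate 1, and 12 of 16 libraries moved it by over 1.5 times. Mix gave 1 gene in the kidney, Dbp, at 1.79 (adjusted p = 0.0201), with 2.19 in males and 0.40 in females; the count ran from 0 without male vehicle replicate 1 to 65 without female vehicle replicate 1 (edgeR; unadjusted 1180 and DESeq2 46 with all libraries).

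Testis transcripts stood in male kidney libraries at levels that differed between the treatment groups, and 225 of the 283 genes higher in Mix than in BPA were testis-enriched. Across testis-enriched genes, their excess over female kidney in vehicle males followed their abundance in testis (Spearman rho 0.814), as did the excess of 2 female thyroid vehicle libraries over the other (rho 0.807). With the ribosomal RNA share as a covariate the median Mix against BPA log2 value of the 225 genes went from 3.56 to 4.70. These genes were chosen without the covariate, so the median alone decides little about that share. Testis RNA or reads carried into these libraries may account for the testis transcripts, since their excess followed abundance in testis. Carry-over in the other direction may account for the kidney transcript Kap in Mix testis (7.33 ± 5.55 CPM against 0.154 ± 0.181 in vehicle, edgeR adjusted p = 0.227). At which step that happened was not tested, and transcription of these genes by the kidneys of male rats stays open as an untested biological explanation.

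Against vehicle, 1 of 9 clock genes passed in the male liver of Mix rats (Nr1d1) and 2 of 9 in the male kidney (Nr1d1 and Dbp), with camera adjusted p = 0.915 and 0.0688 for the list; the mean log2 value of Nr1d1, Nr1d2, Dbp, Tef, Per3 and Ciart, where tested, minus that of Arntl, Npas2 and Clock, none of which passed there, was 2.06 and 2.36. In the liver, kidney, thyroid and ovary it was 0.388, 0.517, 0.729 and 0.304 in Mix females, and at most 0.944, in the kidney, in BPA females. Without Per3 and Ciart it was 0.384 in the Mix kidney, -0.192 in the Mix thyroid, -0.212 in the Mix ovary and 0.715 in the BPA kidney of females. In BPA males it was 0.289 in the liver, -0.119 in the kidney and 1.59 in the thyroid (0.224 there without Per3 and Ciart). Its difference between the sexes was not tested. With the ribosomal RNA share as a covariate the male kidney value was 0.947 of that without it. No standard error was computed for this ratio, which argues against that share as the whole cause in that organ. Another phase of the daily clock at collection may account for the pattern and would move every organ with a strong rhythm. The male thyroid gave 2.63 with Per3 and Ciart and 1.53 over Nr1d1, Nr1d2, Dbp and Tef, the genes tested in every organ. The testis gave 0.088 and 0.0994, between the bounds set for a shift and for none. How strong the rhythm is in each organ was not measured, so the testis values cannot decide. The male organs share their sample codes and so appear to come from the same rats. Without collection times another phase cannot be told apart from an effect of the mixture. An effect of the treatment on the clock stays open as untested.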

How the results depend on the processing

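The fits with the ribosomal RNA share as a covariate, without the ribosomal RNA genes and without testis-enriched genes, and for sex-biased sets the replicate block and the left-out libraries, were chosen after the data were seen. Unless a reason is given below, the cause of a difference was not tested.

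With DESeq2's size factors in the edgeR fit, 249 of 252 tests of named genes and 117 of 118 gene lists stayed on their side of the threshold; 2 named genes came under it and 1, Olfml2b, and 1 list, the lymphocyte markers in Mix against BPA female liver, left it. Counts were within 1.5 times of those given except in the female thyroid for BPA, with 2 genes and an overlap with Mix of 1. Female-biased genes in the liver of BPA females had an adjusted p = 0.0411 by camera. Without the ribosomal RNA genes no count of genes changed by over 1.5 times.

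Without the low-count filter edgeR called 78, 116 and 75 genes in the male liver for BPA, Mix and Mix against BPA, and 229, 109 and 86 in the female liver. It called 191 for BPA and 13 for Mix in the male kidney, 258, 72 and 12 in the female kidney, 1 in the female thyroid for BPA, 4 for Mix and 258 for Mix against BPA in the testis, and 85 for Mix against BPA in the ovary. Of the 258 genes in the female kidney for BPA, 0 were among those the filter removes, and of the 229 in the female liver 4 were (edgeR; at an unadjusted p below 0.05 with the filter 1754 and 1092, and by DESeq2 314 and 185), so most came from genes tested in both fits. Sex differences numbered 91 for BPA and 74 for Mix in the liver and 5 for Mix in the kidney. Overlaps of BPA and Mix were 42 in the male liver, 59 in the female liver, 3 in the male kidney, 38 in the female kidney and 1 in the female thyroid. The correlation of male and female changes was 0.0228 for BPA and 0.00899 for Mix in the liver, -0.0239 and 0.109 in the kidney and 0.370 for Mix in the thyroid, over a wider set of genes by construction. By camera, male-biased genes had an adjusted p = 0.00495 in the liver of Mix males and 0.05002 in the kidney of BPA females. Of named genes 16 came under the threshold and 236 stayed, and 7 of 118 lists left it.

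DESeq2's Wald test called more genes than edgeR: 65, 95 and 48 in the male liver for BPA, Mix and Mix against BPA, 185, 56 and 34 in the female liver, 822, 97 and 714 in the male kidney and 314, 68 and 12 in the female kidney. It called 16, 35 and 114 in the male thyroid, 223, 1386 and 40 in the female thyroid, 104, 19 and 447 in the testis, and 1163 for BPA and 280 for Mix against BPA in the ovary. Sex differences numbered 80 and 50 in the liver, 1264 and 46 in the kidney and 237 and 54 in the thyroid for BPA and Mix. Of named genes 34 came under the threshold, 214 stayed and 1, Serpina11 in the ovary of BPA rats, left it.

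With the replicate number as a block the male liver gave 2 genes for Mix against BPA, the female liver 19 for BPA and 5 for Mix against BPA, the male kidney 168 for BPA and 26 for Mix with an overlap of 2, and the female thyroid 3 for Mix. It gave 0 genes by edgeR for Mix against BPA in the testis (1913 unadjusted and 447 by DESeq2 without it) and 0 for the Mix sex difference in the kidney (1180 and 46). The correlation of male and female BPA changes in the thyroid was -0.0753. By camera, female-biased genes had an adjusted p = 0.0308 in the liver of BPA females and 0.174 in the kidney of Mix males, and male-biased genes 0.0538 in the kidney of BPA females. Of named genes 22 left the threshold, including Mx2 and Dusp1 in the ovary of BPA rats and Fst in that of Mix rats, 2 came under it and 228 stayed; 4 lists left it and 114 stayed. The block changed no other count by over 1.5 times.

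With the ribosomal RNA share as a covariate the male liver gave 2 genes for Mix against BPA, the female liver 21 for BPA, the male kidney 1 for BPA and 5 for Mix, the female kidney 994, 403 and 1 for BPA, Mix and Mix against BPA, the testis 546 for Mix against BPA, and the ovary 96, 616 and 11. Sex differences numbered 13 for BPA and 12 for Mix in the liver and 1 for BPA in the kidney. It gave 0 by edgeR for Mix in the female thyroid (2561 unadjusted and 1386 by DESeq2 without it). Without testis-enriched genes the male kidney gave 1 gene for BPA and 8 for Mix against BPA, and the female thyroid 2 for BPA. Of the 15 and 322 genes called in the male kidney with all genes, 7 and 225 were testis-enriched; the cause of the further fall was not tested. By camera, female-biased genes then had an adjusted p = 0.0380 in the liver of BPA females and 0.0847 in the kidney of Mix males; male-biased genes had 0.103 in the kidney of BPA females and 0.459, with the direction reversed, in that of BPA males.

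With a correlation estimated from the data 117 of 118 lists left the threshold and 1 stayed. Female-biased genes in the liver of Mix males had an adjusted p = 0.215. In the kidney, both sets had 0.236 in BPA males, male-biased genes 0.236 in BPA females, both sets 0.405 in Mix males and both 0.236 in Mix females.

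Leaving out 1 library at a time, which also lowers the number of samples, gave these lowest and highest edgeR counts for BPA, Mix and Mix against BPA: male liver 3 to 41, 10 to 57 and 0 to 6; female liver 8 to 41, 0 to 11 and 0 to 7; male kidney 0 to 886, 2 to 19 and 20 to 653; female kidney 0 to 806, 0 to 329 and 0 to 1; female thyroid 0 to 1119 for BPA and 0 to 2093 for Mix; testis 0 to 420, 0 to 1 and 0 to 994; ovary 184 to 892, 263 to 1177 and 0 to 38. With all libraries the unadjusted counts of these comparisons were 591 to 2767 and those by DESeq2 12 to 1423. A female kidney group left with 1 library is assumed to vary like the other groups. Sex differences ran from 5 to 69 and 7 to 36 in the liver for BPA and Mix, 2 to 1259 and 0 to 65 in the kidney, and 0 to 725 and 0 to 396 in the thyroid. Overlaps ran from 0 to 26 in the male and 0 to 7 in the female liver, 0 to 9 and 0 to 296 in the kidney, 0 to 989 in the female thyroid, 0 to 1 in the testis and 110 to 485 in the ovary.

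The correlation of male and female changes ran, without 1 library, from -0.00887 to 0.131 for BPA and 0.0119 to 0.133 for Mix in the liver, -0.260 to -0.146 and -0.0597 to 0.0795 in the kidney, and -0.460 to 0.292 and 0.348 to 0.586 in the thyroid. The adjusted p-values by camera of female-biased genes in the liver ran from 0.00897 to 0.761 in BPA males, 0.000882 to 0.829 in BPA females, 1.35e-08 to 0.0649 in Mix males and 0.0150 to 0.977 in Mix females, and those of male-biased genes from 0.000257 to 0.605 in Mix males. In the kidney, female-biased genes ran from 7.05e-07 to 0.881 in BPA males, 0.00192 to 0.710 in BPA females, 3.78e-07 to 0.718 in Mix males and 3.90e-36 to 0.589 in Mix females, and male-biased genes from 0.00521 to 0.589 in BPA females, 0.000108 to 0.827 in Mix males and 1.02e-07 to 0.589 in Mix females. The direction of 6 lists reversed without 1 library, with these adjusted p-values: the CAR and PXR targets in the female liver for BPA (1.20e-05 to 0.893) and Mix against BPA (1.15e-07 to 0.860), the loop of Henle markers (3.10e-06 to 0.987 for BPA) and proximal tubule markers (2.80e-11 to 0.769 for Mix) in the female kidney, the cell cycle genes in the male thyroid for Mix against BPA (3.19e-05 to 0.810) and the skeletal muscle markers in the female thyroid for Mix against BPA (2.94e-12 to 0.605). Of 213 named results past the threshold, 78 stayed past it without each single library and 135 did not.

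With 4803807 to 10929957 counts per library, 9554 to 11127 of 17048 genes passed the filter in an organ and sex, and genes below it were not tested. Above a floor of mean count, the recovered share of simulated 2-fold changes ran from 1% in the male thyroid to 64% in the testis. Counts of genes in different organs are therefore not on 1 scale. How far depth, rather than the spread between rats, limits these shares was not tested.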

Other observations

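Of the tests in this part, the effect of the ribosomal RNA share, the counts without testis-enriched genes, the size of the changes and the other groupings without a vehicle library, the comparison of Cyp17a1 between libraries and the other groupings were chosen after the results were seen; the count without a vehicle library was chosen before.

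Several genes passed in more than 1 organ or in both sexes. Orm1 rose in the male liver of BPA and Mix rats and in the female liver of BPA rats (2.62, 1.94 and 2.61 log2 units) and fell in the ovary of both treated groups (-3.73 and -2.23). Hsd11b1, which regenerates active glucocorticoid, rose in the female liver of BPA rats (2.61; edgeR adjusted p = 0.0141) and fell in their ovaries (-1.33; adjusted p = 0.038). Cdkn1a fell in the male liver of Mix rats (-2.46; adjusted p = 0.00431) and in the ovary of BPA rats (-1.31; adjusted p = 0.0192). Mst1, a plasma growth factor, fell in the liver of BPA rats of both sexes (-1.14 and -1.15; adjusted p = 0.0261 and 0.0394). Mst1, and Cdkn1a, Hsd11b1 and Orm1 where the naming rule did not pick them, were chosen after their values were seen. Differences between organs were not tested.

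In the ovary Myh6, a heart muscle myosin, rose from 0.255 ± 0.312 to 16.1 ± 6.80 CPM in BPA and 13.2 ± 4.79 CPM in Mix rats (edgeR adjusted p = 0.000695 and 0.00116). Cthrc1, a secreted collagen-associated protein, fell from 38.4 ± 6.98 to 2.35 ± 2.44 and 2.95 ± 1.02 CPM, and Sfrp4, a Wnt antagonist of the corpus luteum, from 147 ± 76.2 to 21.9 ± 8.72 and 24.2 ± 1.73 CPM.

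By edgeR with no covariate, most calls against vehicle were in the ovary; without testis-enriched genes, some of them read in vehicle ovaries, the counts were 762 for BPA and 1005 for Mix. With the ribosomal RNA share as a covariate the median absolute log2 value of the called genes was 0.976 of its value in BPA (0.882 to 0.861) and 0.953 in Mix (0.844 to 0.805). These genes were chosen without the covariate, so the ratios alone decide little. The counts fell to 96 and 616. In Mix, 564 of 991 calls stayed, with a median standard error of 0.187 before and 0.19 after. This argues against that share as the whole cause in Mix. In BPA, 81 of 738 calls stayed as that error grew from 0.186 to 0.264, so there the share stays open. Without each vehicle library in turn edgeR still called 255 to 553 genes for BPA and 275 to 867 for Mix, where other groupings of the 5 libraries left gave at most 15, which argues against 1 vehicle library as the whole cause. Whether 1 library added to the calls stays open: the lowest Mix count, 275 of 991, was below the bound set for that, but leaving out a Mix library gave 263, a condition considered only after the values were seen, and the median size of the changes, 0.961 to 1.08 of that with all libraries, was taken over genes chosen with all of them and decides nothing. A different cycle stage in the vehicle rats may account for the pattern: Cyp17a1 lay above every vehicle library in 6 of 6 treated libraries, which an effect of the treatment would give too, so these cannot be told apart without recorded stages.

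Other groupings of the 6 libraries of a comparison number 10, too few for a share under 0.05, so only the real value and the highest other are given. The real grouping was the 1 with as many genes in the male liver for BPA (22, highest other 3) and Mix (31 and 5), the female liver for BPA (40 and 9) and Mix (5 and 1), the male kidney for BPA (15 and 1), Mix (3 and 1) and Mix against BPA (322 and 1), the female thyroid for Mix (1 and 0), and the ovary for BPA (738 and 0), Mix (991 and 0) and Mix against BPA (23 and 4). For Mix against BPA, 3 groupings gave as many in the male liver (1 and 2) and 2 in the testis (86 and 99). All 10 did so where edgeR's real count was 0, which that count fixes, given with the count at an unadjusted p below 0.05, the DESeq2 count and the highest other: the female liver for Mix against BPA (621, 34 and 2), the male thyroid for BPA (915, 16 and 1), Mix (551, 35 and 0) and Mix against BPA (1533, 114 and 0), the female thyroid for BPA (1485, 223 and 0) and Mix against BPA (650, 40 and 1), and the testis for BPA (1337, 104 and 254) and Mix (591, 19 and 1). The 254 genes in the testis point to a structure of those samples apart from the treatment groups.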
